A study of Mus musculus with 18 samples.

How the data were processed

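RNA from mouse cumulus cells was measured on 18 Affymetrix Mouse 430 2.0 arrays, 1 array per sample, after repeated amplification of total RNA, per the labels' protocols. The 6 groups of 3 arrays were taken from the sample titles. They are intact cumulus-oocyte complexes, complexes from which the oocyte had been removed, and such oocyte-free complexes cultured together with oocytes, each with and without estrogen. Nothing in the labels says that the 3 samples of a group came from separate animals or cultures, so every p-value measures only the spread between these samples, which may be technical. The title of 1 array placed it in the oocyte-free group with estrogen (replicate 1), while its source name and treatment label described oocyte-free complexes without estrogen. The title was followed. The array names in the labels fall into 3 series of 13, 2 and 3 arrays. No array held the same values as another.

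The deposited values are log2 expression values that the authors made with RMA (background correction, quantile normalization and summary per probe set) in Affymetrix Expression Console 1.1, per the submitters' processing notes. They were rounded to 2 decimals in the deposited table. The array medians lay between 5.51 and 5.71 and the interquartile ranges between 2.53 and 3.05. The chip image files were not used here, and no detection calls or background levels were at hand. Quantile normalization gives all arrays a similar distribution, so a shift of most transcripts in 1 direction would not be visible, and low values are compressed towards the background, so that folds of dim genes are understated. The number of arrays limits the precision. The genome build is not given in the sources used here, so no coordinates are given.

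The table held 45101 probe sets, of which 64 were Affymetrix controls. Of the probe sets, 34945 carried 1 gene symbol in the platform annotation, 932 carried several and 9160 had none listed. Symbols of 34741 probe sets were brought up to date through their Entrez identifiers with a RefSeq table of the assembly GRCm38.p6, which was used for names and for the order of neighbouring genes alone. Probe sets with several symbols were left out. Each of 18193 genes was represented by the probe set with the highest mean over the 18 arrays, so that other probe sets of a gene can differ from the value given. Genes entered the tests if they lay above the median of all probe sets of an array in at least 3 of the 18 arrays, which left 12252 genes.

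Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on the log2 values, with 6 group means in 1 fit, so that all groups shared 1 estimate of the spread. The 12 contrasts were oocyte removal (oocyte-free minus intact), added oocytes (coculture minus oocyte-free) and coculture minus intact, each without and with estrogen, the estrogen effect in each culture type and averaged over the 3, and 2 interactions of estrogen with oocyte removal and with added oocytes. Adjusted p-values are Benjamini-Hochberg values over all tested genes, and a gene was called where the adjusted p was under 0.05. A gene called higher is said to have risen and a gene called lower to have fallen. Each log2 change is followed by its standard error (SE) from the fit, with 3 arrays per group. The SE rests on the spread shared by all 6 groups and is not the spread of the compared arrays. A gene has the same SE in each comparison of 2 groups, although oocyte-free arrays spread more than intact ones. Two-sided tests were used throughout unless stated otherwise.

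The groups, the tests, the 16 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The lists covered glycolysis, cholesterol synthesis, amino acid transport, mural granulosa markers, cumulus markers, the cell cycle, the estrogen response, SMAD targets, cumulus expansion, steroid synthesis, hormone and growth factor receptors, cell death, oocyte markers, theca and stroma markers, endothelial and blood cell markers, and immediate early and heat shock genes. Of their 320 entries, 287 matched a gene with a probe set and 228 were tested. Some genes stand on more than 1 list, so the results of different lists are not independent. Lists were tested against the other genes with camera from limma, with an inter-gene correlation of 0.01 and adjustment over the 16 lists of a contrast. Camera with a correlation estimated per list, and fry, which tests whether the members move 1 way on balance and compares them with no other genes, were alternatives. Of 192 list tests, 70 were called with the preset correlation and 18 of these also with an estimated one. The median, the mean and the test direction of a list differed in sign in 1 of the 70 calls and in 36 of the other 122 tests.

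The rule for named genes took, per contrast, the 8 genes with the largest rise and the 8 with the largest fall among called genes whose groups did not overlap (without this condition for the averaged effect and the interactions), up to 4 members of each list with the smallest adjusted p, and a short list of hormone, receptor and metabolic genes. Symbols of unnamed transcripts were left out. The text names part of the genes that this rule gives, and this part was chosen after the values had been seen.

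The alternatives were no filter on dim genes, all probe sets, quantile normalization of the tested genes again, a trended and robust variance, a fit on the compared groups alone, a 2-fold minimum, the replicate set or the array series as a term, both together, the array with conflicting labels left out or placed with its other labels, and each array left out in turn. After the data were seen, fits on series 1 alone, without the series 2 arrays and with limma's array weights were added, and a fit of cocultures and intact complexes with estrogen with the replicate number as a block. In that comparison the deviations of all same-numbered arrays from their group means correlated over 0.1 (0.164, 0.294 and 0.309), a pairing found in the data and not given by the labels, and in no other tested comparison of 2 groups did they. For the comparison of oocyte-free with intact complexes without estrogen, the procedure was tested on simulated data of 12252 genes, 200 of them changed, over 10 simulations. It recovered 9.93% of changes of 0.5 on the log2 scale, 75.2% of changes of 1 and 99.5% of changes of 2, with 4.21% false calls. A shifted list was called in 10 of 10 simulations and the other lists in 5 of 150 tests. The simulated genes varied independently of each other and held no array series effect. In the data the estimated correlation within a list reached 0.541 (glycolysis), so these rates do not carry over to lists whose members vary together.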

Results

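Cumulus cells are the granulosa cells that surround the oocyte in the antral follicle. The study asked how oocytes and estrogen together shape the transcripts of mouse cumulus cells in culture. Messenger RNA was measured on 18 arrays, 3 in each of 6 groups: intact cumulus-oocyte complexes, oocyte-free complexes and cocultures of oocyte-free complexes with oocytes, each without and with estrogen. Over the 12252 genes tested, the first principal component held 55.5% of the variance and separated the 6 oocyte-free arrays from the 12 arrays with oocytes. The second held 14.3% and separated the arrays with estrogen from those without. The median within-group SD of a gene, over 3 arrays, was 0.27 in oocyte-free complexes and 0.16 in intact complexes without estrogen, and 0.23 and 0.15 with estrogen. In cocultures it was 0.20 without and 0.17 with estrogen. Oocyte-free replicate 3 without estrogen stood apart, with an interquartile range of 2.53 against 2.69 to 3.05 on the other arrays and a highest correlation of 0.944 with its own group.

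**Figure D1:**
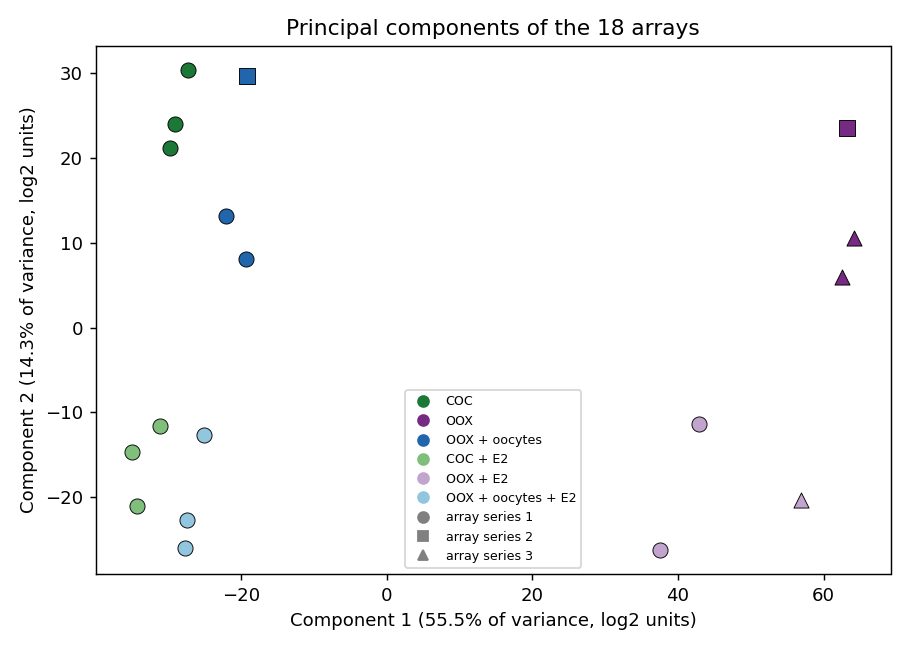
Scores of the 18 arrays on the first and second principal components of the 12252 tested genes (log2 units; 55.5% and 14.3% of the variance). Each point is 1 array, colours mark the 6 groups and shapes the 3 array series. The oocyte-free arrays lie at first-component scores from 37.5 to 64.2 and all other arrays below 0.

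The arrays came in 3 series by their names, and these were unevenly spread over the groups. Series 1 held 13 arrays, among them all intact complexes and all cocultures with estrogen. The 3 oocyte-free arrays without estrogen lay outside series 1, with 1 in series 2 and 2 in series 3. Of the oocyte-free arrays with estrogen, 2 were in series 1 and 1 in series 3, and 1 coculture without estrogen was in series 2.

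The first comparison, of oocyte-free with intact complexes without estrogen, asked what cumulus cells lose or gain once the oocyte is gone. Dnajb13, an axonemal protein gene, fell by 7.08 ± 0.217 on the log2 scale (SE, n = 3 per group), a 136-fold difference. The neutral amino acid transporter gene Slc38a5 changed by -6.28 ± 0.253, the vesicular monoamine transporter gene Slc18a2 by -6.03 ± 0.241 and Tac1, the substance P precursor, by -5.59 ± 0.171. Fbp1, a gluconeogenic enzyme gene, changed by -5.22 ± 0.210 and Ccnd2, which encodes cyclin D2, by -5.14 ± 0.198. In the other direction, the hyaluronan-binding protein gene Cemip rose by 5.04 ± 0.354, the protocadherin gene Pcdh9 by 5.00 ± 0.231, the lipid carrier gene Apoe by 4.89 ± 0.330, the vascular ligand gene Angpt2 by 4.84 ± 0.283 and the proteoglycan gene Dcn by 4.48 ± 0.233. Kitl, the Kit ligand through which granulosa cells act on the oocyte, rose by 4.59 ± 0.364, or 24.1-fold. For each of these genes the 3 arrays of one group did not overlap those of the other, and limma's adjusted p-values lay between 3.61e-13 and 3.3e-08. The rule for the largest changes asks for a call and for no overlap, so neither adds support to the genes it picked.

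Genes of cell division and of sterol synthesis fell together on oocyte removal. All 32 tested cell cycle genes fell (32 adjusted over the list alone), with a list median of -2.59. The proliferation marker Mki67 fell 14.0-fold, the replicative helicase gene Mcm5 8.26-fold and Birc5, which encodes survivin, 7.24-fold. Of 19 cholesterol synthesis genes, 18 fell and 1 was not called (18 adjusted over the list alone), with a median of -2.05. Among them, the farnesyl diphosphate synthase gene Fdps fell 9.51-fold, Msmo1 8.50-fold and Mvd 6.29-fold. Camera gave adjusted p-values of 2.23e-21 for the cell cycle and 4.77e-13 for cholesterol synthesis, and 0.0390 for each with an estimated correlation.

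Glycolysis and amino acid uptake genes were also lower in oocyte-free complexes. Of 15 glycolysis genes, 10 fell and 3 rose (10 and 4 adjusted over the list alone). Aldoc changed by -3.38 ± 0.282, Ldha, a lactate dehydrogenase gene, by -1.79 ± 0.144, and Pfkp, a phosphofructokinase gene, by -1.76 ± 0.297. The list median was -1.07, with a camera adjusted p of 0.0159, and adjusted p = 0.767 with an estimated correlation. Of 17 amino acid transporters, 11 fell and 1 rose (the same numbers adjusted over the list alone), among them Slc38a3, a glutamine transporter of cumulus cells, 5.64-fold lower. Their median was -1.06, with an adjusted p of 0.000492, and adjusted p = 0.0974 with an estimated correlation.

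Markers of both granulosa cell types fell more often than they rose. Of 10 cumulus markers, 7 fell and none of them rose (7 adjusted over the list alone), with a median of -1.59 and an adjusted p of 0.000470. Of 13 mural granulosa markers, 8 fell and 1, Kitl, rose (the same numbers adjusted over the list alone), with a median of -0.99 and an adjusted p of 0.000859. Inhbb, an activin subunit gene, changed by -4.67 ± 0.323, the estradiol-forming enzyme gene Hsd17b1 by -4.24 ± 0.206 and Fst, which encodes the activin antagonist follistatin, by -3.31 ± 0.206. Nppc, the precursor of the peptide that acts on the receptor NPR2 of cumulus cells, fell by 1.91 ± 0.210. With an estimated correlation the adjusted p was 0.0304 for cumulus and 0.0390 for mural markers. The cumulus list shares Slc38a3, Pfkp, Ldha, Cyp51, Sqle and Ube2c with the metabolic and cell cycle lists above. The mural list shares Star, Cyp11a1, Cyp19a1 and Hsd17b1 with the steroid synthesis list. In this and the later comparisons these marker lists are therefore not separate evidence from the lists that share their genes.

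Of 13 cell death genes, 5 rose and none fell (5 adjusted over the list alone), among them the pro-apoptotic gene Bmf at 2.44 ± 0.363 and the cell cycle inhibitor gene Cdkn1a at 1.79 ± 0.185. The list median was 0.39, with an adjusted p of 0.0159, and adjusted p = 0.355 with an estimated correlation. The SMAD targets went both ways, 8 up and 5 down of 18 (the same numbers adjusted over the list alone; camera adjusted p = 0.642). Id1, a target of BMP signalling, rose 9.54-fold, while Pmepa1, a target and feedback inhibitor of TGF-beta signalling, fell 11.2-fold. Of 19 receptor genes, 5 rose and 3 fell (6 and 3 adjusted over the list alone; adjusted p = 0.710), with the estrogen receptor gene Esr1 at -2.43 ± 0.310 and the FSH receptor gene Fshr at -1.32 ± 0.267. The Fshr call ended with the array series as a term, at -0.87 (adjusted p = 0.102; from 7.2e-05 to 0.121 over its alternatives).

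The remaining lists were not called on oocyte removal without estrogen. Of 18 estrogen response genes, 5 rose and 4 fell (6 and 4 adjusted over the list alone; adjusted p = 0.812). Of 6 cumulus expansion genes, 3 rose and 2 fell (3 and 2 adjusted over the list alone; adjusted p = 0.780). Of 10 steroid synthesis genes, 3 rose and 3 fell (the same numbers adjusted over the list alone; adjusted p = 0.985). Of 17 immediate early and heat shock genes, 5 rose and 6 fell (5 and 7 adjusted over the list alone; adjusted p = 0.985). Of 9 theca and stroma markers, 2 rose and 4 fell (3 and 4 adjusted over the list alone; adjusted p = 0.985), Dcn being higher and the Hedgehog pathway genes Gli1 and Ptch1 lower, at -1.68 ± 0.176 and -1.22 ± 0.177. None of 5 endothelial and blood cell markers was called (0 adjusted over the list alone; adjusted p = 0.828). Of 7 tested oocyte markers, Bcl2l10, a BCL2 family gene, fell 15.0-fold and the other 6 were not called (1 adjusted over the list alone; adjusted p = 0.828). Gdf9, an oocyte growth factor gene, stood at 6.88 ± 0.0321 in intact and 6.94 ± 0.286 in oocyte-free complexes (log2, SD, n = 3 each).

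In all, 4746 of 12252 genes passed the limma test on oocyte removal without estrogen, 2208 higher and 2538 lower, and 2101 of them by at least 2-fold. No array series held both groups, so no value within a series could be had for this comparison. With the series as a term in the fit, 3124 genes were called.

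The second comparison asked how far added oocytes bring back the transcripts of oocyte-free complexes. Without estrogen, Dnajb13 was 122-fold higher in cocultures than in oocyte-free complexes, Slc38a5 76.1-fold and Tac1 54.4-fold, and Slc18a2 rose by 6.13 ± 0.241. Cemip fell 28.5-fold, Pcdh9 28.4-fold, Apoe 19.6-fold and Kitl 13.4-fold. Fdps rose by 2.83 ± 0.218, Mki67 by 3.57 ± 0.270, Ldha by 1.83 ± 0.144 and Slc38a3 by 2.59 ± 0.192 (SE, n = 3 per group). Esr1 rose by 2.54 ± 0.310, Fshr by 1.65 ± 0.267 and Bcl2l10 by 3.71 ± 0.339, while Id1 and Cdkn1a changed by -3.36 ± 0.171 and -1.59 ± 0.185.

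The gene groups turned with them. All 32 cell cycle genes rose (32 adjusted over the list alone), with a median of 2.23. Of 19 cholesterol synthesis genes, 18 rose (18 adjusted over the list alone; median 1.83), and of 17 amino acid transporters 11 rose and 1 fell (12 and 1 adjusted over the list alone; median 0.87). Of 13 mural markers, 8 rose and 1 fell (the same numbers adjusted over the list alone; median 1.02), and of 10 cumulus markers 6 rose (6 higher and 1 lower adjusted over the list alone; median 1.58). Camera gave these lists adjusted p-values from 4.64e-21 to 0.00179, and from 0.0335 to 0.0493 with an estimated correlation. Of 15 glycolysis genes, 10 rose and 3 fell (the same numbers adjusted over the list alone; median 1.21, adjusted p = 0.00197, and adjusted p = 0.553 with an estimated correlation). Of 13 cell death genes, 6 fell and 2 rose (the same numbers adjusted over the list alone; median -0.49, adjusted p = 0.0366, and adjusted p = 0.470 with an estimated correlation). With the array series as a term, the cell death call ended (adjusted p = 0.0901; from 0.0343 to 0.470 over its camera alternatives, while fry, against no change, gave 0.00584).

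In all, 4068 genes passed on adding oocytes without estrogen, 2428 higher and 1640 lower. After a second quantile normalization of the tested genes the split was 2146 higher and 2271 lower. With the array series as a term, 3309 genes were called. Of the 4746 genes called on oocyte removal, 3614 (76.1%) were called in the opposite direction on adding oocytes, and 798 would be shared by independent lists. Both comparisons use the same oocyte-free arrays. Over all tested genes their changes correlated at r = -0.962 and had a covariance of -0.660, against r = -0.498 and a covariance of -0.0236 in 20 simulations without effects. The simulations and the count for independent lists leave out any array series effect. The simulations also give all groups the same spread. The shared oocyte-free arrays spread more (median SD 0.27) than intact complexes (0.16) and cocultures (0.20), so the simulated r and covariance understate the built-in part. All 3 of these oocyte-free arrays lay outside series 1, so a series shift in them would also give opposite changes. Against the estrogen-treated cocultures and oocyte-free complexes, which share no array with it, oocyte removal without estrogen still had 2340 genes called in the opposite direction and 23 in the same one (r = -0.815; 590 for independent lists). Genes are not independent replicates, and these correlations are across genes.

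**Figure D2:**
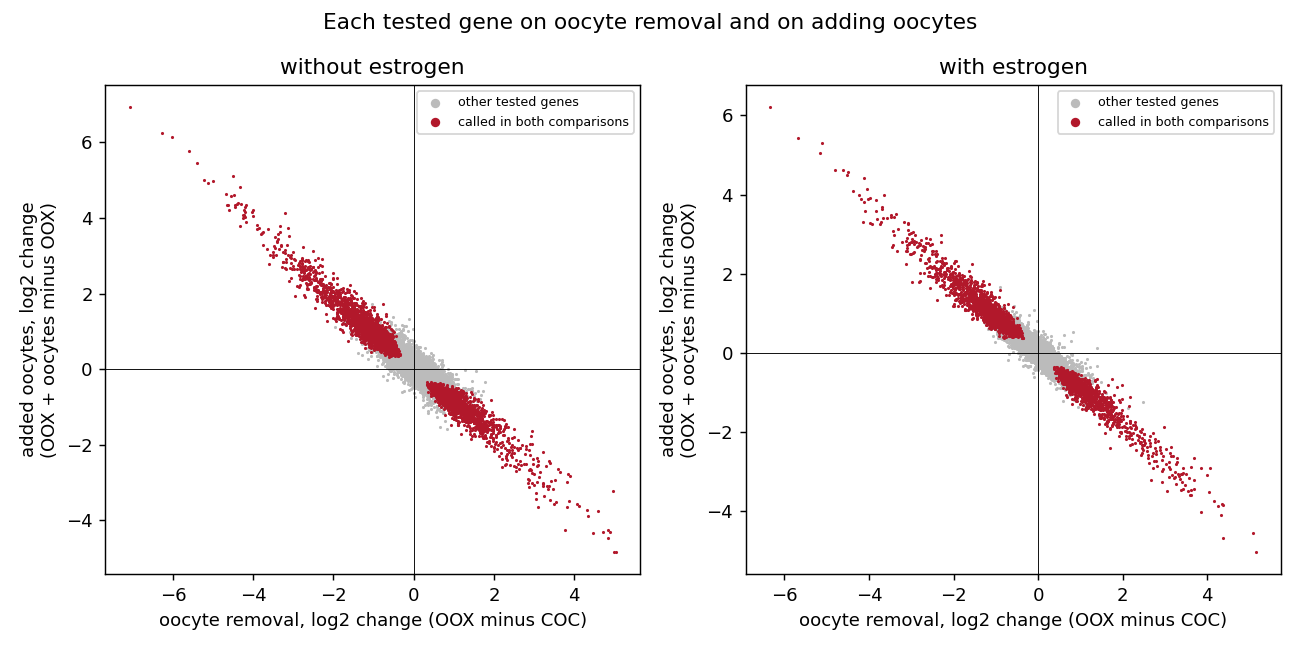
Log2 change of each of the 12252 tested genes on oocyte removal (x axis) and on adding oocytes (y axis), without estrogen (left) and with estrogen (right). Red points are genes called in both comparisons. The points lie along a falling diagonal, with r = -0.962 without and -0.970 with estrogen, and part of this relation comes from the oocyte-free arrays that both axes share.

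The third comparison set cocultures directly against intact complexes. Without estrogen, 1 gene passed, Filip1l, a filamin-interacting protein gene, 2.83-fold higher in cocultures (n = 3 per group; limma adjusted p = 0.0495), and 733 genes had an unadjusted p under 0.05. That call ended in several alternatives, among them the fit on these groups alone (adjusted p = 0.370; from 2.79e-05 to 0.796 over its alternatives), and with 13 of the 18 arrays left out in turn. Within array series 1, 13 genes were called, and 153 with array weights. With estrogen, limma called 0 genes, with 346 at an unadjusted p under 0.05 and 93 called with array weights. With the replicate number as a block, 1 gene was called over all arrays (Ddit4, picked after its value was seen; adjusted p = 0.0211) and 20 in a fit of these groups alone, 15 higher and 5 lower. Both groups lay in series 1 there. Without any difference, a share of 0.05 of the 12252 genes would have an unadjusted p under 0.05. The 733 genes lay above that share and the 346 below it. The shared spread takes in the oocyte-free arrays, which spread more, so small differences may have been missed in these 2 comparisons.

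Few single genes were called, and with estrogen the lists called went both ways. Cholesterol synthesis genes had a median of -0.28 without and -0.36 with estrogen in cocultures against intact complexes (0 of 19 called; 0 and 2 lower adjusted over the list alone), with camera adjusted p-values of 1.08e-05 and 2.66e-13, and adjusted p = 0.708 and 0.135 with an estimated correlation. Cell cycle genes had medians of -0.16 and -0.30 (0 of 32 called; 0 and 0 adjusted over the list alone), with adjusted p-values of 0.000128 and 1.02e-10, and adjusted p = 0.708 and 0.135 with an estimated correlation. Without estrogen the cell cycle call ended with the array series as a term (median -0.01, adjusted p = 0.144). With estrogen 4 more lists were called: cumulus markers with a median of -0.18, SMAD targets 0.13, immediate early and heat shock genes 0.25, and theca and stroma markers with a median of -0.08 but a mean of 0.20. Their adjusted p-values lay between 0.000399 and 0.0435, and between 0.135 and 0.203 with an estimated correlation. The theca and stroma call also ended with the array series as a term (adjusted p = 0.0900). Each cell cycle and cholesterol synthesis call, and those of the 4 lists, was also lost with fry. The other 10 lists were not called with estrogen and the other 14 not without it.

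The fourth comparison repeated oocyte removal in the presence of estrogen. Inhbb fell by 6.34 ± 0.323, or 81.2-fold, and Dnajb13 and Fbp1 changed by -5.68 ± 0.217 and -5.15 ± 0.210 (SE, n = 3 per group). The actin-binding thymosin gene Tmsb4x rose by 5.16 ± 0.278, the guanine nucleotide exchange factor gene Fgd5 by 5.07 ± 0.205 and the growth factor gene Bmp2 by 4.35 ± 0.198. Kitl rose by 3.10 ± 0.364 and Dcn by 3.39 ± 0.233. Esr1 changed by -1.52 ± 0.310, Fshr by -2.02 ± 0.267, Ldha by -0.88 ± 0.144 and Slc38a3 by -0.90 ± 0.192. Bcl2l10 fell 20.7-fold.

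Again all 32 cell cycle genes fell (32 adjusted over the list alone), with a median of -1.57 and Mcm3 at -2.35 ± 0.206. Of 19 cholesterol synthesis genes, 18 fell (19 adjusted over the list alone), with a median of -2.40, Fdps at -3.43 ± 0.218 and Dhcr7, the gene of the last step of the pathway, at -2.55 ± 0.142. Of 10 cumulus markers, 7 fell (7 adjusted over the list alone; median -1.07), and of 13 mural markers 7 fell and 1 rose (8 and 1 adjusted over the list alone; median -0.87), with Hsd17b1 at -3.70 ± 0.206. Camera gave these lists adjusted p-values from 1.1e-17 to 0.000633, and from 0.0119 to 0.0392 with an estimated correlation.

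A further 6 lists were called on oocyte removal with estrogen, each of which lost its call with an estimated correlation. Of 15 glycolysis genes, 10 fell and 2 rose (the same numbers adjusted over the list alone), with Aldoc at -2.97 ± 0.282 (adjusted p = 0.00274, and adjusted p = 0.370 with an estimated correlation). Of 17 amino acid transporters, 8 fell (9 lower and 1 higher adjusted over the list alone; adjusted p = 0.00274, and adjusted p = 0.132 with an estimated correlation). Of 10 steroid synthesis genes, 6 fell (6 adjusted over the list alone), with the nuclear receptor gene Nr5a2 at -1.55 ± 0.256 (adjusted p = 0.0263, and adjusted p = 0.0907 with an estimated correlation). Of 13 cell death genes, 5 rose (5 adjusted over the list alone), with Bmf 16.6-fold higher (adjusted p = 0.0130, and adjusted p = 0.260 with an estimated correlation). Of 9 theca and stroma markers, 5 rose and 1 fell (the same numbers adjusted over the list alone), with Dcn and the smooth muscle actin gene Acta2, at 2.98 ± 0.315, among the former (adjusted p = 0.00316, and adjusted p = 0.0762 with an estimated correlation). Of 17 immediate early and heat shock genes, 7 rose and 3 fell (the same numbers adjusted over the list alone), with the transcription factor gene Egr1 at 3.09 ± 0.195 (adjusted p = 0.0158, and adjusted p = 0.282 with an estimated correlation).

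With estrogen, 3705 genes passed on oocyte removal, 1585 higher and 2120 lower. Within array series 1 (3 intact and 2 oocyte-free arrays) 4000 were called, and 4067 with the series as a term. Of the genes called on oocyte removal without estrogen, 2760 were called in the same direction with estrogen and 35 in the opposite one (r = 0.813 across genes, no shared arrays; 725 for independent lists).

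The fifth comparison added oocytes in the presence of estrogen. Inhbb rose 74.0-fold, Dnajb13 43.4-fold, Fbp1 33.4-fold, Bcl2l10 16.9-fold, Fdps 6.63-fold and Mki67 4.44-fold (n = 3 per group). Tmsb4x fell 33.0-fold, Fgd5 23.5-fold, Kitl 8.84-fold and Egr1 7.41-fold. In all, 3014 genes passed, 1744 higher and 1270 lower, with 3254 called within array series 1 and 3297 with the series as a term. Of the 3705 genes called on oocyte removal, 2765 (74.6%) were called in the opposite direction, and 466 would be shared by independent lists. Here r was -0.970 and the covariance -0.521, against -0.498 and -0.0236 in simulations without effects. These simulations give all groups the same spread, although the shared oocyte-free arrays spread more, so they understate the built-in part.

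Of 19 cholesterol synthesis genes, 17 rose (17 adjusted over the list alone; median 2.07), of 10 cumulus markers 8 (8 adjusted over the list alone; median 0.95) and of 13 mural markers 7, with 1 lower (8 and 1 adjusted over the list alone; median 0.54). These 3 lists were called by camera (adjusted p from 5.73e-17 to 0.000296) and with an estimated correlation (from 0.0138 to 0.0316). The cell cycle list, with 30 of 32 genes risen (31 adjusted over the list alone; median 1.33, adjusted p = 8.55e-16), missed the threshold there, with adjusted p = 0.0529 with an estimated correlation. Glycolysis (10 of 15 risen, 1 fallen; 11 and 1 adjusted over the list alone), amino acid transport (7 of 17 risen; 7 adjusted over the list alone), steroid synthesis (4 of 10 risen, 1 fallen; 5 and 2 adjusted over the list alone), cell death (3 of 13 fallen; 3 adjusted over the list alone) and theca and stroma markers (4 of 9 fallen, 1 risen; 6 and 1 adjusted over the list alone) were also called. Their camera adjusted p-values lay between 0.000193 and 0.0495, and between 0.0884 and 0.291 with an estimated correlation. The steroid synthesis call ended with the array series as a term (adjusted p = 0.0625) and with the replicate number as a block (adjusted p = 0.0506; from 0.0338 to 0.111 over its camera alternatives, while fry, against no change, gave 2.56e-06).

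**Figure D3:**
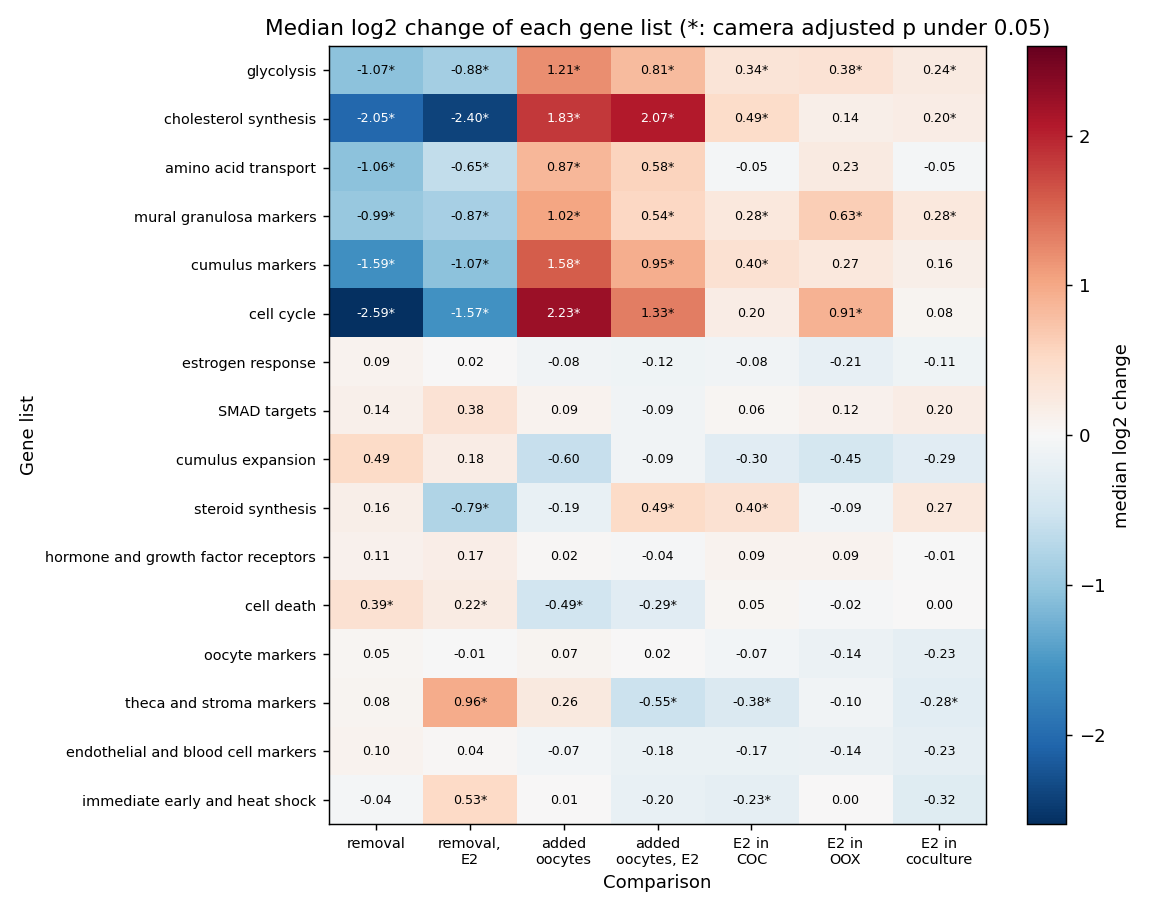
Median log2 change of the tested members of each of the 16 gene lists (y axis) in 7 comparisons (x axis). Colour and number give the median, and a star marks a camera adjusted p under 0.05 with the preset correlation. The cell cycle median was -2.59 on oocyte removal without estrogen and 2.23 on adding oocytes.

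The sixth question was what estrogen does to cumulus cells that keep their oocyte. In intact complexes, the noncoding RNA gene Rian rose 13.8-fold, the transcriptional corepressor gene Cbfa2t3 12.8-fold, the water channel gene Aqp8 8.94-fold and the fibrillin gene Fbn2 8.32-fold (n = 3 per group). The type IV collagen gene Col4a1 fell 12.0-fold, Acta2 10.2-fold, Igfbp7, which encodes an insulin-like growth factor binding protein family member, 10.1-fold and the proteoglycan gene Cspg4 8.94-fold. Npr2, the natriuretic peptide receptor gene, rose by 2.06 ± 0.221, Slc38a3 by 1.45 ± 0.192, the activin subunit genes Inhba and Inhbb by 2.11 ± 0.182 and 2.36 ± 0.323, and the steroidogenic transcription factor gene Nr5a1 by 2.28 ± 0.320. Gli1 changed by -1.88 ± 0.176, Ptch1 by -1.52 ± 0.177 and the smooth muscle gene Tagln by -1.65 ± 0.254.

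Of 18 preset estrogen response genes, 3 rose and 1 fell in intact complexes (the same numbers adjusted over the list alone; camera adjusted p = 0.918). Greb1, an estrogen receptor target in breast cells, rose by 0.82 ± 0.143, the growth factor gene Tgfa by 1.32 ± 0.235 and the nuclear receptor corepressor gene Nrip1 by 0.72 ± 0.176, while Igfbp4 fell by 1.41 ± 0.342. The Nrip1 call ended after a second quantile normalization (0.61, adjusted p = 0.0741) and without intact replicate 2 or 3 or estrogen-treated replicate 2 or 3, and the Igfbp4 call without intact replicate 1 or 2 or estrogen-treated replicate 3. Over their alternatives the adjusted p ran from 0.00158 to 0.124 for Nrip1 and from 0.00112 to 0.242 for Igfbp4. Esr1 was not called (-0.20 ± 0.310), nor was Nppc (-0.14 ± 0.210). The lists called higher were mural markers (2 of 13 risen; 5 adjusted over the list alone; median 0.28), cumulus markers (2 of 10 risen; 4 adjusted over the list alone; median 0.40), cholesterol synthesis (3 of 19 risen, with Lss at 0.87 ± 0.144; 6 adjusted over the list alone; median 0.49), steroid synthesis (2 of 10 risen, Nr5a1 and the lipoprotein receptor gene Scarb1; 3 adjusted over the list alone; median 0.40) and glycolysis (0 of 15 called; 0 adjusted over the list alone; median 0.34). Their adjusted p-values were 0.000235 to 0.0196, and adjusted p = 0.0791 to 0.482 with an estimated correlation. Called lower were theca and stroma markers, whose 4 fallen members of 9 were Acta2, Tagln, Gli1 and Ptch1 (4 adjusted over the list alone; median -0.38), and immediate early and heat shock genes, with 5 of 17 fallen, Egr1 among them at -1.38 ± 0.195, and 1 risen (6 and 2 adjusted over the list alone; median -0.23). Their adjusted p-values were 0.000235 and 0.00207, and adjusted p = 0.0791 and 0.206 with an estimated correlation.

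Among lists without a call, 2 of 17 amino acid transporters rose and 1, Slc38a4 at -1.40 ± 0.222, fell in intact complexes (the same numbers adjusted over the list alone; camera adjusted p = 0.868). Of 6 cumulus expansion genes, 2 fell, one of them the transcription factor gene Runx1 at -1.12 ± 0.199 (3 lower and 1 higher adjusted over the list alone; adjusted p = 0.120). In all, 709 genes passed, 423 higher and 286 lower, against 380 and 395 after a second quantile normalization. All 6 arrays lay in series 1. Within that series 1446 genes were called in a fit whose shared spread came from the series 1 arrays, and 437, 472 and 383 were called without intact replicate 1, estrogen-treated replicate 2 and estrogen-treated replicate 3.

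In cocultures estrogen changed 570 genes, 284 higher and 286 lower (373 without estrogen-treated coculture replicate 3). Cbfa2t3 rose 11.9-fold, Rian 7.26-fold and Fbn2 6.92-fold, while Col4a1 fell 20.2-fold, Igfbp7 10.9-fold, Col4a2 8.67-fold, Cspg4 8.02-fold and Acta2 6.01-fold (n = 3 per group). Npr2 rose by 2.14 ± 0.221, Inhba by 2.06 ± 0.182, Slc38a3 by 1.53 ± 0.192, Nr5a1 by 1.88 ± 0.320 and Greb1 by 0.79 ± 0.143, and Gli1 and Ptch1 changed by -1.99 ± 0.176 and -1.35 ± 0.177. Nppc was not called (0.17 ± 0.210). Of the genes called in intact complexes, 418 were called in cocultures in the same direction and 0 in the opposite one (r = 0.814 across genes, no shared arrays; 16.5 for independent lists). Mural markers (3 of 13 risen; 3 adjusted over the list alone) and theca and stroma markers (4 of 9 fallen; 4 adjusted over the list alone) were called with adjusted p-values of 0.000702 and 0.000271, and 0.0465 for each with an estimated correlation. Cholesterol synthesis (2 of 19 risen; 4 adjusted over the list alone) and glycolysis (0 of 15 called; 0 adjusted over the list alone) were called with adjusted p-values of 0.00270 and 0.0130, and adjusted p = 0.414 and 0.555 with an estimated correlation. Within series 1, 838 genes were called, and 756 with the series as a term.

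In oocyte-free complexes estrogen changed 1181 genes, 738 higher and 443 lower. The signalling regulator gene Rgs13 rose 21.4-fold, Crh, which encodes corticotropin-releasing hormone, 14.6-fold, Fbn2 13.7-fold, Hsd11b2, which encodes a glucocorticoid-inactivating enzyme, 10.4-fold and Slc38a3 8.24-fold (n = 3 per group). Cemip fell 10.9-fold, Tgfbi, a TGF-beta-induced matrix gene, 9.94-fold, Igfbp4 5.92-fold and Runx1 4.43-fold. Inhba rose by 1.44 ± 0.182, Npr2 by 1.56 ± 0.221, Nppc by 1.53 ± 0.210, Ldha by 1.20 ± 0.144 and Acta2 by 1.54 ± 0.315. Greb1 and Esr1 were not called, at 0.35 ± 0.143 and 0.70 ± 0.310. Esr1 was called without the arrays of series 2, at 1.25 (adjusted p = 0.000116; from 0.000116 to 0.783 over its alternatives), without oocyte-free replicate 3 alone and with array weights. Dcn and Ptch1, at -1.14 ± 0.233 and 0.73 ± 0.177, lost their calls with the array series as a term, at -0.81 and 0.62, and in the fit on these groups alone (adjusted p = 0.108 and 0.116; from 0.000111 to 0.790 and from 0.00248 to 0.629 over their alternatives). Ptch1 also lost its call without oocyte-free replicate 2 or estrogen-treated replicate 1. The Acta2 rise was not called in the fit on these groups alone either (adjusted p = 0.0765; from 6.73e-05 to 0.755 over its alternatives).

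Of 32 cell cycle genes, 18 rose with estrogen in oocyte-free complexes (22 adjusted over the list alone), with a median of 0.91, the ribonucleotide reductase gene Rrm2 at 1.74 ± 0.224 and the mitotic kinase gene Cdk1 at 1.40 ± 0.235. Of 13 mural markers, 5 rose (7 adjusted over the list alone; median 0.63), and of 15 glycolysis genes 5 rose and 1 fell (6 and 2 adjusted over the list alone; median 0.38). Camera gave adjusted p-values of 1e-12, 0.00177 and 0.0219, and adjusted p = 0.177, 0.134 and 0.722 with an estimated correlation. The other 13 lists were not called in oocyte-free complexes. With the array series as a term 620 genes were called, 526 of them among the 1181, and the fit on these groups alone called 209. Within series 3 there was 1 array with and 2 without estrogen, and no other series held both groups. Of the genes called without series 3, 68.4% differed in the same direction within it. Those calls rested on 1 oocyte-free array without estrogen, of series 2, against 2 with estrogen, of series 1. The call count was 777 without oocyte-free replicate 2 and 526 without replicate 1 with estrogen, the array whose labels conflict, and 0 when that array was placed in the group without estrogen.

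Averaged over the culture types, estrogen changed 2800 genes, 1513 higher and 1287 lower (1814 with the array series as a term). Changes of the average included Fbn2 at 3.21 ± 0.141, the glutathione peroxidase gene Gpx3 at 2.71 ± 0.309, Slc38a3 at 2.01 ± 0.111, Npr2 at 1.92 ± 0.128, Inhba at 1.87 ± 0.105, Greb1 at 0.65 ± 0.0827, Col4a1 at -3.21 ± 0.183 and Igfbp7 at -2.99 ± 0.112 (SE, 9 arrays with and 9 without estrogen). Of these genes, Greb1 was not called in oocyte-free complexes, and the effects on Slc38a3, Col4a1 and Igfbp7 differed in size between oocyte-free complexes and both other cultures. Of the preset lists, the cell cycle (15 of 32 risen; 18 higher and 1 lower adjusted over the list alone), glycolysis (8 of 15 risen; 11 and 1), cholesterol synthesis (8 of 19 risen; 9 and 0), mural markers (6 of 13 risen; 8 and 0) and cumulus markers (5 of 10 risen, 2 fallen; 5 and 3) were called higher. Theca and stroma markers (5 of 9 fallen, 1 risen; 5 lower and 1 higher adjusted over the list alone) were called lower. Their camera adjusted p-values were 1.77e-05 to 0.0345, and adjusted p = 0.0535 to 0.379 with an estimated correlation. Of these lists, glycolysis and mural markers alone were called in each culture type. The cell cycle was called in oocyte-free complexes only (median 0.91, against 0.20 in intact complexes and 0.08 in cocultures). Cumulus markers were called in intact complexes only. Cholesterol synthesis and theca and stroma markers were not called in oocyte-free complexes.

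**Figure D4:**
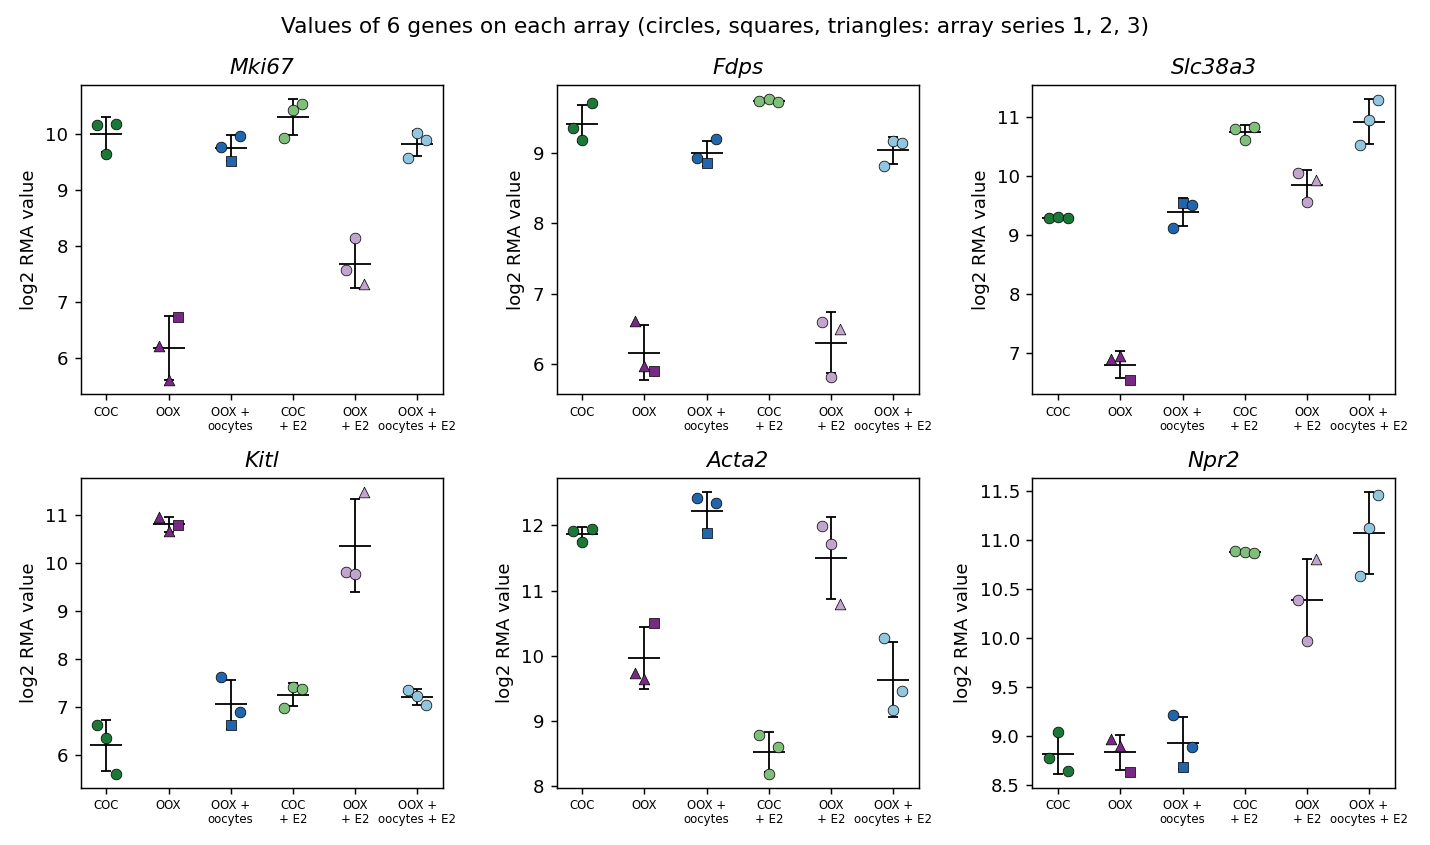
Log2 values of Mki67, Fdps, Slc38a3, Kitl, Acta2 and Npr2 on each of the 18 arrays; points are arrays, shapes the array series, horizontal bars group means and error bars the SD over 3 arrays. Mki67 averaged 10.0 in intact and 6.19 in oocyte-free complexes without estrogen. Acta2 fell with estrogen from 11.9 to 8.52 in intact complexes and rose from 9.96 to 11.5 in oocyte-free ones.

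The last comparison tested whether the estrogen effect itself depended on oocytes. It differed between oocyte-free and intact complexes in 393 genes, 219 with a higher and 174 with a lower change in oocyte-free complexes. The difference was 4.88 ± 0.445 for Acta2, which estrogen lowered in intact and raised in oocyte-free complexes, 4.63 ± 0.483 for the sphingosine phosphatase gene Sgpp2 and 3.64 ± 0.378 for Crh. It was -3.47 ± 0.344 for the surface protein gene Cd83, -3.56 ± 0.521 for the RNA-binding protein gene Rbfox3, -3.38 ± 0.378 for the corepressor gene Tle2 and -3.25 ± 0.501 for Cemip. Ptch1 and Gli1 differed by 2.24 ± 0.250 and 1.34 ± 0.249, Slc38a3 by 1.59 ± 0.271, Nppc by 1.67 ± 0.296 and Ldha by 0.91 ± 0.203 (n = 3 per group; limma adjusted p from 8.21e-06 to 0.0166). The Ldha difference was not called without estrogen-treated intact replicate 2 or 3 (adjusted p = 0.0509 and 0.0525; from 0.00667 to 0.772 over its alternatives). The count was 689 without oocyte-free replicate 3 with estrogen, and 383 with the array series as a term.

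Between cocultures and oocyte-free complexes the estrogen effect differed in 341 genes, 109 higher and 232 lower with oocytes. Acta2 differed by -4.13 ± 0.445, Sgpp2 by -4.57 ± 0.483, Crh by -3.67 ± 0.378, Filip1l by -3.55 ± 0.321, Ptch1 by -2.07 ± 0.250, Slc38a3 by -1.51 ± 0.271 and Ldha by -1.02 ± 0.203, while Cd83 and Tle2 differed by 2.96 ± 0.344 and 2.81 ± 0.378. The count was 542 without oocyte-free replicate 3 without estrogen and 494 with the array series as a term. Of the cell cycle genes, 2 of 32 had a higher estrogen effect in oocyte-free than in intact complexes (10 adjusted over the list alone) and 6 a lower one in cocultures than in oocyte-free complexes (13 adjusted over the list alone). Camera gave adjusted p-values of 6.56e-09 and 4.72e-11, and adjusted p = 0.263 and 0.165 with an estimated correlation.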

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

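The tests by other splits of the arrays, of the calls kept with the series as a term, of the array with conflicting labels and of oocyte RNA were chosen after the results they bear on had been seen. What drew attention to the genes and lists named first was a test of the difference itself: the estrogen effect in oocyte-free complexes differed from that in intact complexes in 393 genes, and from that in cocultures in 341. In the next sentences the first value of a gene is the estrogen effect in oocyte-free minus that in intact complexes, and the second that in cocultures minus that in oocyte-free complexes (log2, n = 3 per group). Both differences use the same oocyte-free arrays, so opposite signs in them are partly built in. The array series, the conflicting labels and Bcl2l10 were not picked by such a test.

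The genes are grouped by function for order alone. The estrogen effect was higher in oocyte-free complexes than in both other cultures for Acta2 at 4.88 and -4.13, Tagln at 1.53 and -1.78, Tmsb4x at 1.77 and -2.61 and Filip1l at 2.03 and -3.55. A higher effect was not always a rise: in oocyte-free complexes Tagln, Tmsb4x and Gli1 were at -0.12, -0.37 and -0.54 with estrogen and not called. Col4a1, given below, was called lower there (-1.72, limma adjusted p = 0.00231), so its higher effect was a smaller fall. The effect was also higher for the amino acid transporters Slc38a3 (1.59 and -1.51), Slc38a4 (2.56 and -2.93) and Slc38a5 (1.67 and -1.63), and for the Hedgehog pathway genes Ptch1 (2.24 and -2.07) and Gli1 (1.34 and -1.46). Among genes of the basement membrane and of the vessel wall, Col4a1 differed by 1.86 and -2.61, Cspg4 by 1.98 and -1.82 and Igfbp7 by 1.13 and -1.24. Peptide and growth factor genes followed, with Crh at 3.64 and -3.67, Tac1 at 1.07 and -1.28, Nppc at 1.67 and -1.36 and Bmp2 at 1.11 and -1.64. Signalling genes were Rgs13 (2.75 and -3.02), Fgd5 (2.17 and -2.28), Egr1 (1.55 and -1.92) and Pmepa1 (2.12 and -2.03). Enzyme genes were Sgpp2 (4.63 and -4.57), Hsd11b2 (2.38 and -2.0), Ldha (0.91 and -1.02) and Rrm2 (1.34 and -1.68), and Dnajb13 differed by 1.40 and -1.49.

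The opposite pattern, a lower estrogen effect in oocyte-free complexes, was seen for the regulators of transcription and RNA Cbfa2t3 (-2.49 and 2.38), Tle2 (-3.38 and 2.81), Id1 (-1.0 and 1.53) and Rbfox3 (-3.56 and 2.92). It was also seen for Aqp8 (-2.89 and 2.49), Cd83 (-3.47 and 2.96), Cemip (-3.25 and 3.08) and Tgfbi (-2.46 and 2.61). Rian (-2.19) and Dhcr7 (-0.80) differed between oocyte-free and intact complexes, and Birc5 (-1.05), Cdk1 (-1.56) and Col4a2 (-1.47) between cocultures and oocyte-free complexes.

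Of the preset lists, the estrogen effect was higher in oocyte-free than in intact complexes for the cell cycle (median difference 0.82, camera adjusted p = 6.56e-09), theca and stroma markers (0.66, adjusted p = 0.0044) and immediate early and heat shock genes (0.30, adjusted p = 0.0044). It was lower for cholesterol synthesis (-0.48, adjusted p = 0.0129) and steroid synthesis (-0.49, adjusted p = 0.00753). Between cocultures and oocyte-free complexes it was lower with oocytes for the cell cycle (-0.85, adjusted p = 4.72e-11), theca and stroma markers (-0.52, adjusted p = 0.00426) and amino acid transport (-0.38, adjusted p = 0.0368) and higher for steroid synthesis (0.24, adjusted p = 0.0368). With an estimated correlation none of these calls held, with adjusted p = 0.147 to 0.526 for the first 5 lists and adjusted p = 0.162 to 0.391 for the other 4. With fry, the calls of the cell cycle, cholesterol synthesis and immediate early and heat shock genes for the first difference and of amino acid transport for the second ended too (adjusted p = 0.0741, 0.240, 0.0741 and 0.0561). Amino acid transport also lost its call with the array series as a term (-0.16, adjusted p = 0.0663) and with the replicate block (adjusted p = 0.0573).

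Other splits of the same arrays were fitted in the same way. A comparison of 3 with 3 arrays has 10 splits, too few for a share under 0.05. As many genes as in the real split were called in 1 of 10 splits for oocyte removal without estrogen (4746, highest other 0) and with it (3705, highest other 0), and for added oocytes without (4068, highest other 0) and with estrogen (3014, highest other 0). The same held in 1 of 10 for estrogen in intact complexes (709, highest other 1) and in coculture (570, highest other 1). For cocultures against intact complexes it was 2 of 10 without estrogen (1, highest other 1) and 10 of 10 with it (limma called 0 genes in each, with 346 at an unadjusted p under 0.05 in the real split). For estrogen in oocyte-free complexes it was 2 of 10 (1181, highest other 1232), and the larger split set the 3 arrays of series 3 against those of the other series. With the series as a term 620 genes were called, 526 of them among the 1181. For estrogen averaged over culture types 1 of 100 relabellings, the real one, called as many (2800, highest other 1380), a share under 0.05. This share holds for the labels of these arrays alone. The arrays of a group may differ only technically, and the series are unevenly spread over the groups. Chance between separate cultures is therefore not excluded. For the difference between oocyte-free and intact complexes 3 of 100 relabellings called as many genes as the real one (393, highest other 1055). These relabellings exchange estrogen labels within a culture type, so they also break the estrogen effect that the cultures share. They cannot decide whether the difference between cultures came by chance, and no conclusion is drawn from them. The highest count came from the relabelling by series 3 and points to a structure of the samples. With the series as a term 383 genes were called. For the difference between cocultures and oocyte-free complexes it was 6 of 100 (341, highest other 1652), and for the same reason these relabellings cannot decide about chance. The highest count there came from exchanging the estrogen labels of all cocultures, several times the real count, and points to a structure of the samples, the estrogen effect shared by both culture types; 494 genes were called with the series as a term.

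The difference between oocyte-free and intact complexes without estrogen lay across array series, since no series held both groups. In series 2, which held 1 oocyte-free array and 1 coculture, 87.41% of the 5051 genes that differed in this pair did so in the direction called without series 2 (r = 0.865 across genes), well above the even share that series alone would have given. With estrogen, where 2 oocyte-free and 3 intact arrays shared series 1, 87.51% of these genes moved the same way (r = 0.812). These values argue against the series as the whole cause. The pair held 1 array on each side and a coculture in place of an intact complex, so a part played by the series stays open, and a response to the loss of the oocyte remains a hypothesis.

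The estrogen effect in oocyte-free complexes rested on arrays spread unevenly over the series, and on 1 array with conflicting labels. Over 418 genes that estrogen moved the same way in intact complexes and cocultures, this array lay at 1.23 on a scale from the oocyte-free mean (0) to the mean of the other 2 estrogen-treated arrays (1), while the oocyte-free arrays lay between -0.103 and 0.050. This argues against the reading that the array was cultured without estrogen. Within series 3, 68.37% of the genes called without that series differed in the called direction (r = 0.557 across genes). This lay between the values set for a series effect and for none, with 1 array on one side and 2 on the other. Without series 3, the oocyte-free group without estrogen kept 1 array, replicate 3 of series 2, which stood apart from its group. It was set against 2 arrays of series 1, among them the array with conflicting labels. Of the 1181 calls, 526 were kept with the series as a term. These genes were picked by passing that fit, which takes a series to shift all groups alike. Their number therefore does not decide whether the series was a cause. The calls may come in part from the series, and a biological difference in the response also stays open.

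Bcl2l10, on the preset list of oocyte markers, fell by 3.91 without and by 4.37 with estrogen on oocyte removal. Oocyte RNA in the cumulus samples would have brought the other abundant oocyte transcripts along. The 28 measured markers had a median change of 0.06, with quartiles of -0.05 and 0.29, and of -0.03 with estrogen (quartiles -0.10 and 0.06). Without estrogen, Gdf9 averaged 6.88 in intact and 6.94 in oocyte-free complexes (log2), and with estrogen it changed by -0.01 on removal. The 27 markers other than Bcl2l10 lay between -0.20 and 0.51 without and between -0.75 and 0.34 with estrogen. The lowest with estrogen were Kit at -0.75, Ooep at -0.49 and Dazl at -0.38, which go with the direction of oocyte RNA but stay far from -4.37. This argues against oocyte RNA, and expression of Bcl2l10 in cumulus cells under the influence of the oocyte is a hypothesis that was not tested further.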

How the results depend on the processing

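The fits on series 1 alone, without the series 2 arrays, with array weights and with the block on 2 groups alone were chosen after the data had been seen, and all others before. Every named call that changed its direction is given here, and where a count moved, the cause was not tested unless stated. Of the 179 named gene values, 175 kept direction and side of the threshold with the array series as a term, 178 after a second quantile normalization, without the filter on dim genes, with all probe sets and without the array with conflicting labels, 179 with a trended and robust variance, 169 with the 2-fold minimum and 77 of 77 within series 1. Leaving out each array in turn kept 3195 of 3222 values, with 24 weaker, 1 stronger and 2 reversed.

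The reversed values were of uncalled genes. Gdf9, at 0.0667 on oocyte removal, was at -0.0628 with the series as a term, -0.0567 without oocyte-free replicate 3 and without the series 2 arrays, -0.045 with series and replicate block together, and -0.0167 with the conflicting array moved, and leaving out single arrays gave -0.0567 to 0.223. Nppc in coculture, at 0.173, was at -0.0133 without estrogen-treated coculture replicate 1, and up to 0.302 without replicate 2.

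With the array series as a term, 3124 genes were called on oocyte removal without estrogen, 7 in cocultures against intact complexes without estrogen, 1209 for estrogen in intact and 620 in oocyte-free complexes, and 1814 averaged. With a 2-fold minimum, which by its construction can only lower counts, removal and added oocytes gave 2101 and 1761 without estrogen and 1621 and 1302 with it, genes reversed by added oocytes 1547 and 1213, and estrogen 339 in intact complexes, 439 in oocyte-free complexes, 309 in coculture and 236 averaged. All probe sets gave 4296 averaged. Cocultures against intact complexes without estrogen had 0 limma calls with all probe sets, without the filter, on the groups alone and with the conflicting array moved (1 call and 733 genes at an unadjusted p under 0.05 otherwise). The groups alone gave 1423 for estrogen in intact and 209 in oocyte-free complexes, and 199 for the interaction with added oocytes. Without the conflicting array, 526 genes were called for estrogen in oocyte-free complexes. Moving it to the group without estrogen gave 0 there, 448 in intact complexes, 1072 averaged, and 90 and 87 for the interactions with removal and with added oocytes, with 37 named values weaker.

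Series 1 alone gave 13 calls in cocultures against intact complexes without estrogen and 1446 for estrogen in intact complexes. Without the series 2 arrays these were 10 and 1167, and the interactions 599 and 638. Array weights, lowest for oocyte-free replicate 3 at 0.148, gave 153 and 93 in cocultures against intact complexes without and with estrogen, 2215, 2683 and 1936 for estrogen in intact complexes, oocyte-free complexes and coculture, 4791 averaged, and 1325 and 1557 for the interactions. Of the list tests, 70 were called, and 18 with an estimated correlation. Of the 70 calls, 65 were kept with the array series as a term, 54 with fry and 70 without the array with conflicting labels.

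The numbers in the titles did not pair the arrays throughout: of 45 correlations between same-numbered arrays of 2 groups, 14 were over 0.1 (range -0.327 to 0.422), and 8 of 18 arrays matched best with their own number. In 3 of 15 pairs of groups all were over 0.1, and of these 1 was a comparison tested, cocultures against intact complexes with estrogen. The replicate block gave 0 calls in cocultures against intact complexes without estrogen and 1 with it (20 with the block on these groups alone), and 68 of the 70 list calls. Block and series together gave 3161 on removal, 9 and 1 in cocultures against intact complexes, 1274 and 529 for estrogen in intact and oocyte-free complexes, and 1703 averaged. The block changed no other count by over 1.5 times.

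Leaving out single arrays gave 3977 to 4915 on removal and 3224 to 4257 on adding oocytes without estrogen, and 2870 to 4273 and 2245 to 3600 with it. Genes reversed by added oocytes numbered 2990 to 3768 without and 2160 to 3267 with estrogen. Cocultures against intact complexes gave 0 to 4 without estrogen and 0 to 0 with it. Estrogen gave 383 to 1005 in intact complexes, with 437, 472 and 383 without intact replicate 1, estrogen-treated replicate 2 and estrogen-treated replicate 3. In oocyte-free complexes it gave 526 to 1620, with 777 without replicate 2 and 526 without estrogen-treated replicate 1, in coculture 373 (without estrogen-treated replicate 3) to 800, and averaged 2009 to 3068. The interactions gave 268 to 689 (without estrogen-treated oocyte-free replicate 3) for removal and 233 to 542 (without oocyte-free replicate 3) for added oocytes. No detection calls were used here, so how far dim genes lie above background is unknown, and their folds are understated.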

Other observations

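Each of the gene groups below was picked after its leading members had been seen, and the tests were run on members not yet looked at, with predictions written before. Each prediction of a shared fall asked for a median under -0.3 and a one-sided camera test past 0.05. Values of Meg3, Mirg and Dlk1 and of the members of these groups are given outside the rule for named genes and were chosen after their values were seen. The 3 added lists were tested by camera in 12 contrasts, and adjusted p-values of lists here are over these 36 tests.

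Some genes of the contractile apparatus fell with estrogen in intact complexes and cocultures, while most members were not called. Acta2, Tagln, Mylk, Cald1, Tmsb4x, Myocd and Palld had been seen to fall in intact complexes and were left out of the test. Of the 17 other smooth muscle contractile genes, 4 fell and none rose: the tropomyosin genes Tpm1 (-1.44) and Tpm2 (-0.65), the myosin light chain gene Myl9 (-1.34) and Pdlim7 (-1.28). Both parts of the prediction were met, with a median of -0.3433 (log2, n = 3 per group; camera adjusted p = 9.14e-06, and adjusted p = 0.257 with an estimated correlation). In coculture the median was -0.37, with 3 fallen (adjusted p = 0.000482, and adjusted p = 0.304 with an estimated correlation). In oocyte-free complexes it was 0.36, with Cnn2 (1.1), Actn1 (0.64) and Zyx (0.66) risen (adjusted p = 0.0867). The difference between oocyte-free and intact complexes had a median of 0.57, with 6 genes higher (adjusted p = 4.14e-07, and adjusted p = 0.257 with an estimated correlation). A hypothesis is that estrogen may turn down part of a contractile program where oocytes are present. A lower share of stromal cells would lower their other markers too, and Dcn (-0.05), Pdgfra (0.18), Pdgfrb (1.06), Nr2f2 (-0.38) and Aldh1a1 (0.73) were not called in intact complexes, so that reading was not settled.

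The noncoding RNAs of the imprinted cluster next to Dlk1 rose together with estrogen. In intact complexes Meg3 rose by 2.37, Rian by 3.79 and Mirg by 2.82, in cocultures by 2.20, 2.86 and 2.0, and in oocyte-free complexes by 1.11, 1.60 and 0.82 (log2, n = 3 per group; limma adjusted p from 4.82e-07 to 0.0254). The estrogen effect was lower in oocyte-free than in intact complexes for Rian (-2.19, adjusted p = 0.0118) and Mirg (-2.0, adjusted p = 0.0012), and not called for Meg3 (-1.26, adjusted p = 0.0664). If the whole chromosome region had changed, its other genes would have risen too. The 20 nearest tested genes, 10 on each side, had a median change of 0.0833 in intact complexes (range -0.30 to 0.66), and 1, Dlk1, was called, at 0.66. This argues against a change that reached across these 20 genes. Between the cluster RNAs 0 other genes were tested. Of the closest tested genes on each side, Dlk1 rose and Dio3os was not called (-0.08). A change of the cluster together with its closest neighbours therefore stays open, and a change of the cluster's own RNAs remains a hypothesis.

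Other genes of the Hedgehog pathway did not settle whether the pathway as a whole followed Gli1 and Ptch1. The 10 tested members had a median of -0.1533 in intact complexes with estrogen, which met neither part, and none was called (camera adjusted p = 0.316). In coculture their median was -0.37 (adjusted p = 0.0180, and adjusted p = 0.304 with an estimated correlation), with no single gene called by limma.

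Basement membrane genes other than Col4a1 and Col4a2 went both ways with estrogen in intact complexes. Of 16 tested, the laminin gene Lama1 (-1.10), the nidogen gene Nid1 (-0.96) and Sparc (-1.76) fell and the laminin gene Lama4 (1.24) rose. Their median was -0.2467 (camera adjusted p = 0.0609, and adjusted p = 0.257 with an estimated correlation), short of -0.3, while the one-sided test was past 0.05, so the prediction was met in part and the test left open whether the group fell as a whole.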
